A study of Homo sapiens with 6 samples.

How the data were processed

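The study measured gene expression by RNA sequencing in 6 libraries, 3 labelled as wild-type HG3 and 3 labelled as METTL3 knockout HG3. Total RNA was depleted of ribosomal RNA and made into stranded libraries with an Illumina kit, per the labels' protocol. The submitters' processing notes name STAR, DESeq2 and the build GRCh38 (hg38), without versions; the annotation, the counting program and its strand setting are not given in the sources used here. The deposited table holds 50832 genes by symbol.

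The authors' per-library values are the natural log of a normalized count plus 1, as the values themselves show: undoing the natural log and averaging the 6 libraries gives the deposited baseMean for each gene, with a largest relative difference of 6.17e-09. That baseMean column is a signal, the mean of read counts divided by size factors, per the file headers. The authors' means of each group are also on the natural log scale and were not used. The deposited log2 fold changes and their standard errors, the statistic (a score, the ratio of both), and the p-values and adjusted p-values are the output of the authors' DESeq2 test, per the file headers and the submitters' processing notes. They were used for comparison only.

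Within a library the normalized counts are whole multiples of the value of 1 read, so whole reads could be recovered: 100% of values above 0 lay within 0.1 of a whole number in each library. Depth was 15.5 to 43.2 M reads in the controls and 12.2 to 28.9 M in the knockout, and 1 read is worth 0.515 to 1.59 normalized counts. Size factors by the median of ratios, recomputed from these reads, equal those in the deposited values. An upper limit for a gene at 0 is set at 3 reads of the total. Counts of reads without molecular identifiers are not counts of independent molecules, so this limit covers counting error only.

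Because the deposited values are normalized and on a log scale, the test foreseen for raw counts was not used. Normalized counts were tested with limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), with an intensity trend and robust variance estimates, group as the only term, and a filter of a mean of at least 1 normalized count over the 6 libraries, which left 25361 genes. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. Adjusted p-values are two-sided with the Benjamini-Hochberg procedure at 0.05. On simulated data with 25361 genes, the test recovered 86.6% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold. The changed genes (67, 67 and 66) were drawn from genes with a mean of at least 100, and 4.98% of calls were false. Simulated genes were independent, with the same spread at a given mean in both groups and no library standing apart. The real controls differed more among themselves than the knockout libraries did, so this false share need not hold for the real data.

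A set of 31 gene lists was fixed before the data were examined, as were the groups, the test and all alternatives not marked here as added. Each list was tested with camera at a preset correlation of 0.01, with adjustment over the 31 lists; camera with an estimated correlation and fry were run beside it. None of the lists was called with an estimated correlation. Named genes are METTL3, the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 200 normalized counts and did not overlap between groups (leaving out noncoding, antisense, pseudogene and uncharacterised symbols), and up to 4 members of each list with the smallest adjusted p, or 2 with the highest mean where none passed. CD79A, PAX5, MS4A1, ALAS2, KLF1 and HLA-DRA are list members outside that rule, chosen after their values were seen.

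Symbols were matched to GENCODE 29 on GRCh38 for gene type, position and the GC content and length of the longest transcript: 50805 of 50832 symbols matched, and 50621 matched exactly 1 gene. Another 27 symbols had been turned into dates by spreadsheet software and were tested but not named. Older symbols were found through the reference synonyms. Among the histones 27 of 42 list members found no symbol. GC content and length were known for 99.6% of tested genes.

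Alternatives were trimmed-mean (TMM) and total-count scaling, no filter on low values, a filter of at least 50 in at least 3 libraries, limma-voom on the recovered reads, a replicate block, protein-coding genes only, pseudocounts of 0.1 and 5, leaving out each library, and the authors' deposited test. A mean of at least 10, and a correction of each library for GC content and length by splines with and without control 3, were added after seeing the data. The edgeR fit planned for raw counts was not used, because the unit of the table is the natural log. Figures were drawn with matplotlib 3.10.9.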

Results

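Total RNA was sequenced from 6 libraries labelled as HG3, a cell line derived from chronic lymphocytic leukaemia (CLL), a cancer of B cells. The libraries form 2 groups of 3: a wild-type control and cells in which METTL3, the catalytic subunit of the nuclear complex that methylates adenosine in messenger RNA (m6A), was knocked out. Reads recovered from the deposited values numbered 17.8, 43.2 and 15.5 M (mega) in controls 1, 2 and 3, and 12.2, 28.9 and 17.7 M in knockout replicates 1, 2 and 3. The labels do not say that replicates came from separate cultures, so the p-values given here measure only the spread between these libraries, which may be technical. Groups are called control and knockout by their labels throughout.

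Many genes of the B-cell lineage were scarce in all 6 libraries, and several genes of the red cell lineage were abundant. MS4A1, which encodes the B-cell surface protein CD20, had 0 reads among the 135 M of the 6 libraries together, which allows at most 0.0222 reads per M, counting error only. CD79A, a part of the B-cell receptor, averaged 3.22 ± 1.71 normalized counts in the controls and 1.79 ± 0.818 in the knockout (SD, n = 3 each), and PAX5, a transcription factor of B cells, averaged 1.98 ± 0.712 and 6.02 ± 1.71. By contrast, ALAS2, the erythroid enzyme of haem synthesis, averaged 3637 ± 238 in the controls, and KLF1, an erythroid transcription factor, 2387 ± 178. Of the 28 B-cell identity genes fixed before the data were examined, 16 lay under 10 normalized counts in the controls and 7 at 100 or more; the median was 5.18. Among 15 erythroid and platelet genes, 6 lay under 10 and 7 at 100 or more, with a median of 17.6. Control medians were higher for B-cell receptor signalling (145), plasma cell (73.1) and epithelial and stromal genes (27.9). The abundance of erythroid genes is therefore shown by single genes, not by the list medians. Every direction given here is a difference between libraries labelled HG3 with these levels of lineage genes.

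**Figure D1:**
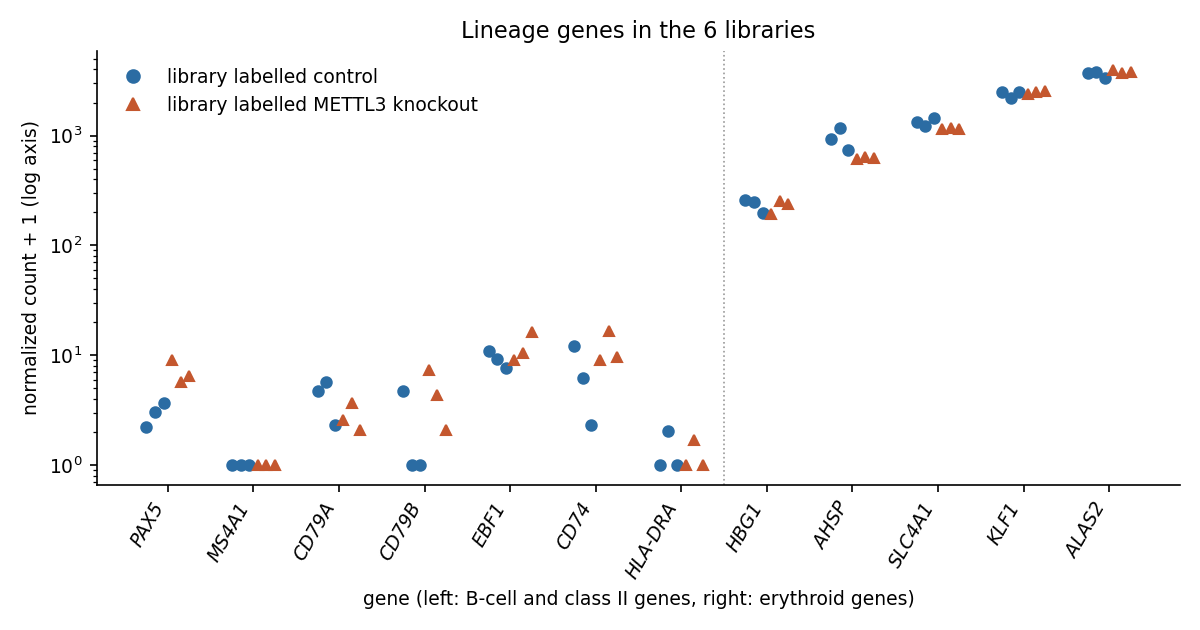
Normalized count plus 1 on a log axis for 7 B-cell and class II antigen presentation genes and 5 erythroid genes in each of the 6 libraries (circles, control; triangles, METTL3 knockout). MS4A1 is at 0 counts in every library, while ALAS2 averages 3637 in the controls. The genes drawn are picked members, not whole lists. In the controls 6 of 15 erythroid and platelet genes lay under 10, and 7 of 28 B-cell identity genes at 100 or more.

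The knocked-out gene itself was checked first. METTL3 (ENSG00000165819.11, chromosome 14, 21498133 to 21511375 on the minus strand of GRCh38, protein-coding) was measured at 1237, 1145 and 1338 normalized counts in controls 1, 2 and 3 and at 989, 979 and 925 in knockout replicates 1, 2 and 3. Its log2 fold change was -0.36 with an SE of 0.09 (limma-trend, adjusted p = 0.0101), with no overlap between the groups. The call was lost without knockout replicate 3 (log2 fold change -0.33, limma-trend adjusted p = 0.0699) and when libraries were scaled by total counts (-0.20, adjusted p = 0.141). A gene-level count can include reads from an edited gene, so this drop tests the labels only weakly.

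In the knockout, 51 of 52 ribosomal protein genes, 43 of 48 genes of respiration, 25 of 30 genes of lipid synthesis and 21 of 31 genes of glycolysis and hypoxia fell, while 22 of 36 interferon-stimulated, 9 of 14 myeloid and 7 of 17 antigen presentation genes rose. Of the 31 lists, 19 were called by camera with a preset correlation and 0 with an estimated correlation. The largest rise among genes with a mean of at least 200 normalized counts was that of MYO1F, a class I myosin of immune cells (chromosome 19, 8520790 to 8577577), from 29.9 ± 3.73 to 464 ± 33.8 normalized counts (SD, n = 3 each). The largest fall among them was that of B3GAT1, the glucuronyltransferase that makes the CD57 epitope (chromosome 11), from 446 ± 81.7 to 76.2 ± 6.72. Of 25361 genes tested, 3513 rose and 3248 fell at an adjusted p of 0.05 (limma-trend), 26.7% in all. Among 11133 genes with a mean of at least 100 normalized counts the balance turned, with 1964 higher and 2756 lower. Over all tested genes, at least 2-fold changes were less even, with 1516 genes higher and 340 lower. Among the 11133 genes these changes numbered 271 higher and 85 lower, so most of the large rises were in genes with lower counts. Values of the groups did not overlap for 41.5% of genes, where chance gives 10%.

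These counts changed with the libraries used. Leaving out control 3 raised them to 5520 and 5220, and leaving out any other library lowered them to a similar range. Without control 1 they were 2566 and 1877, and without control 2 they were 2793 and 2346. Leaving out knockout replicates 1, 2 or 3 gave 2382 and 1974, 2274 and 1990, or 2315 and 1972. The genes lower by at least 2-fold numbered 210 without control 2. Total-count scaling shifted the median of all genes by 0.16 on the log2 scale and gave 5054 genes higher and 1858 lower, so 73.1% of calls were higher against 52.0% with the authors' size factors. A correction for transcript GC content and length, added after the data were seen, tilted the calls the other way, with 3515 genes higher and 4590 lower (43.4% higher). In the authors' deposited table, 2897 genes were higher and 2999 lower at an adjusted p of 0.05; 5759 genes passed in both analyses, all with the same sign.

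Control 3 stood apart from the other controls. Over 12585 genes with a mean of at least 50 counts, the SD of the log2 difference was 0.18 between controls 1 and 2, 0.36 between controls 1 and 3 and 0.39 between controls 2 and 3. Across genes, which are not independent replicates, the difference of control 3 from control 1 correlated with that of the knockout mean from control 2, libraries with no member in common (r = 0.470). In the lowest quintile of transcript GC content the median log2 difference of the knockout was -0.27 against controls 1 and 2 and -0.03 against control 3. For the highest quintile it was 0.29 against controls 1 and 2 and -0.04 against control 3. The lists that passed are therefore given also against control 3 alone, a value with no test, and with the median difference of control 3 from controls 1 and 2 where it had the same sign.

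**Figure D2:**
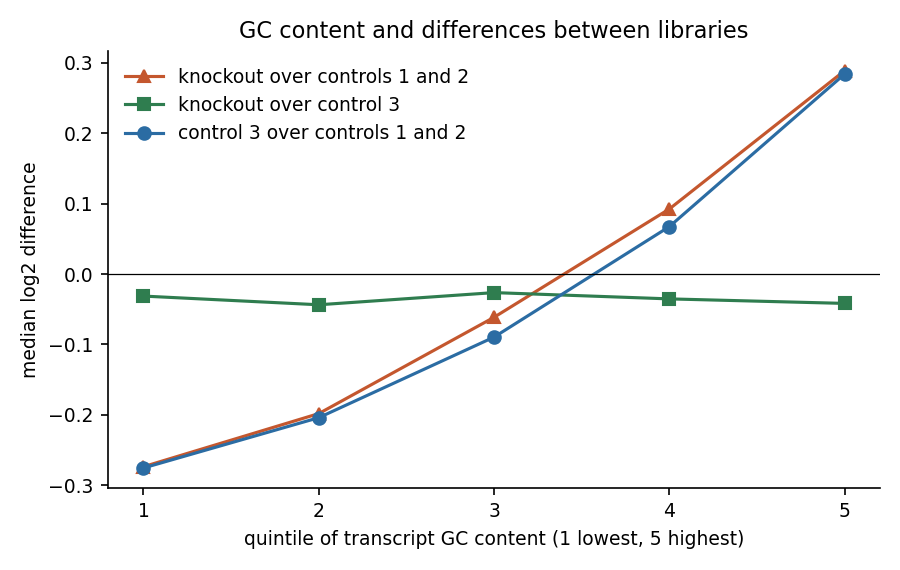
Median log2 difference (vertical axis) by quintile of transcript GC content (horizontal axis, 1 lowest to 5 highest) for the knockout mean over controls 1 and 2 (triangles), the knockout mean over control 3 (squares) and control 3 over controls 1 and 2 (circles). The triangles run from -0.27 to 0.29, and the squares stay between -0.04 and -0.03.

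Other large rises were those of HNMT, which degrades histamine (log2 fold change 3.31, SE 0.16), and of CD84, a receptor of the SLAM family (2.43, SE 0.13). RPP25, a subunit of ribonuclease P, rose from 205 ± 25.5 to 1098 ± 71.2 normalized counts, and TRANK1 from 457 ± 32.2 to 2348 ± 59.5. FAM69A, PHLDA1, PAQR8, PLEKHH2 and LGALS3BP rose by log2 fold changes of 2.36, 2.31, 2.26, 2.23 and 2.12. Among the falls, FLT1, a receptor for vascular endothelial growth factor, had a log2 fold change of -2.07 (SE 0.14), coagulation factor F8 one of -1.77 (SE 0.13) and mitochondrial arginase ARG2 one of -1.61 (SE 0.12). FAM178B, DCHS2 and ALDOC fell by 1.53, 1.47 and 1.32 on the log2 scale. For these 20 genes the adjusted p (limma-trend) ranged from 7.93e-09 for MYO1F to 3.36e-06 for DCHS2. The rule for naming them required an adjusted p under 0.05 and no overlap between the 2 groups.

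**Figure D3:**
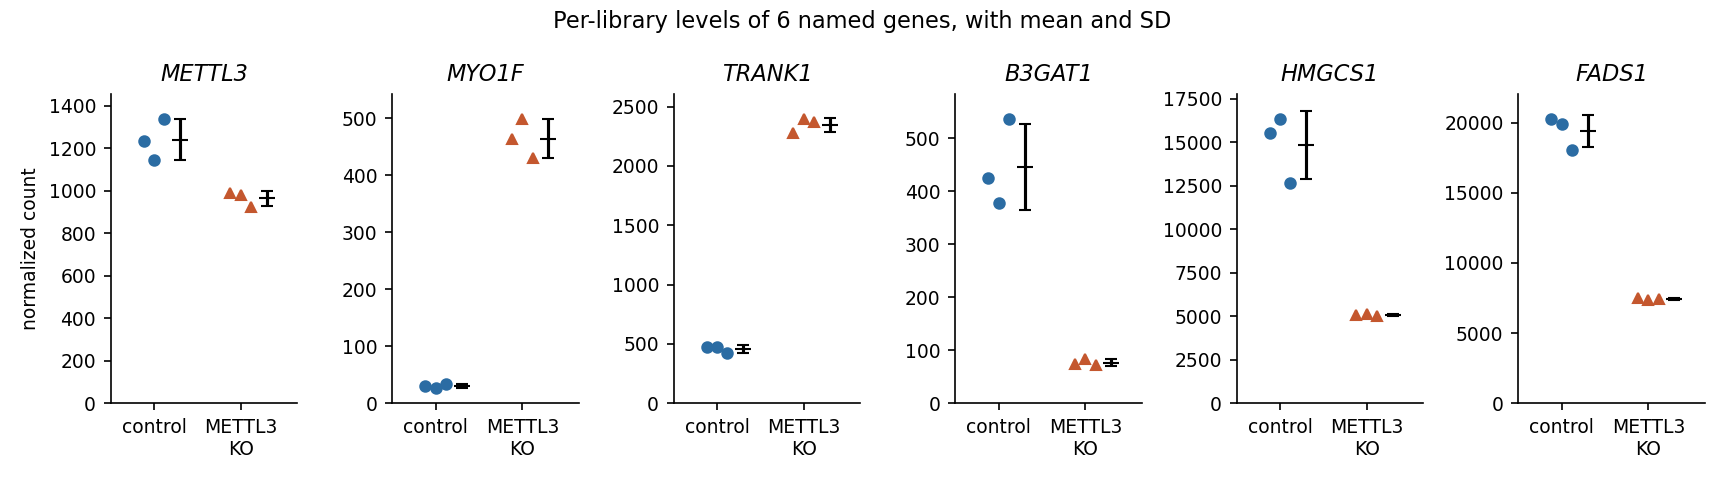
Normalized count (vertical axis) of METTL3, MYO1F, TRANK1, B3GAT1, HMGCS1 and FADS1 in each library (circles, 3 controls; triangles, 3 METTL3 knockout libraries), with the group mean and SD beside the points. METTL3 lies between 925 and 989 in the knockout and between 1145 and 1338 in the controls.

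Cholesterol and fatty acid synthesis genes fell together: 25 of 30 tested were lower and 0 higher (25 and 0 adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 1.18e-20; adjusted p = 0.0713 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, went from 14834 ± 1942 to 5073 ± 75.4 normalized counts, the desaturase FADS1 from 19407 ± 1161 to 7423 ± 56.9, and INSIG1, a regulator of sterol sensing, fell by 1.32 on the log2 scale. MSMO1, of sterol demethylation, fell by 1.42 and the desaturase SCD by 1.08. Control 3 differed from controls 1 and 2 by a median of -0.12, and against control 3 alone the list's median was -0.84.

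Glycolysis and hypoxia genes were lower for 21 of 31 members and higher for 3 (24 and 4 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 6.45e-11; adjusted p = 0.106 with an estimated correlation; -0.53 against control 3 alone, which differed from controls 1 and 2 by -0.19). The aldolase ALDOC, PFKFB4 (-1.15) and the glucose transporter SLC2A3 (-1.06) fell, whereas NDRG1, a gene induced by hypoxia, rose by 1.60. Of 48 nuclear-encoded subunits of oxidative phosphorylation, 43 fell and 0 rose (45 and 1 adjusted over the list alone), among them CYC1 (-0.87), SDHB (-0.67), ATP5PO (-0.65) and ATP5F1B (-0.63). Their median was -0.47 (camera adjusted p = 2.47e-18; adjusted p = 0.2001 with an estimated correlation) and -0.33 against control 3 alone, which differed from controls 1 and 2 by -0.25. In the unfolded protein and integrated stress response list 16 of 33 members fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 4.27e-07; adjusted p = 0.2001 with an estimated correlation; -0.29 against control 3 alone, which differed from controls 1 and 2 by -0.18). The members DDIT4 (-1.18), the cystine transporter SLC7A11 (-1.07), the serine synthesis enzyme PHGDH (-1.05) and asparagine synthetase ASNS (-0.94) fell. With total-count scaling the respiration and stress response medians were -0.31 and -0.22.

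Cytosolic ribosomal protein genes fell for 51 of 52 members and rose for 0 (52 and 0 adjusted over the list alone), by a median of 0.66 on the log2 scale (camera adjusted p = 3.52e-27; adjusted p = 0.213 with an estimated correlation). RPL24 went from 6115 ± 896 to 3065 ± 48.9 normalized counts, and RPL14 (-0.79), RPL27 (-0.68) and RPL8 (-0.64) fell. Control 3 differed from controls 1 and 2 in the same direction (median -0.37), and against control 3 alone the median was -0.42. Ribosome biogenesis genes associated with MYC fell for 21 of 35 members and rose for 3 (21 and 5 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 2.23e-05; adjusted p = 0.2001 with an estimated correlation; -0.26 against control 3 alone, which differed from controls 1 and 2 by -0.18). NPM1 (-0.81), FBL (-0.64), NOP58 (-0.52) and LYAR (-0.51) fell, and total-count scaling brought that median to -0.13. Ribosomal protein genes and NPM1 have many processed copies in the genome, so their counts are uncertain to the extent that the authors' counting split reads between copies.

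Splicing factors, which the series title names, were measured in 3 lists, and more members fell than rose in each. Of 60 core spliceosome genes, 26 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 2.62e-07; adjusted p = 0.169 with an estimated correlation; -0.19 against control 3 alone, which differed from controls 1 and 2 by -0.15). LSM4, a component of U6 particles, went from 2875 ± 206 to 1768 ± 44.5, and SNRPG (-0.65), SNRPB (-0.64) and PLRG1 (-0.63) fell. SR proteins and related regulators fell for 15 of 32 tested and rose for 1 (18 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 6.72e-05; adjusted p = 0.171 with an estimated correlation; -0.18 against control 3 alone, which differed from controls 1 and 2 by -0.08). SRSF3 (-0.47), LUC7L2 (-0.42), SRSF9 (-0.41) and TRA2A (-0.40) were among them. For hnRNPs, 22 of 31 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.73e-08; adjusted p = 0.162 with an estimated correlation; -0.29 against control 3 alone, which differed from controls 1 and 2 by -0.17). HNRNPH1 went from 11666 ± 623 to 7614 ± 39.8, and HNRNPH3 (-0.60), HNRNPAB (-0.53) and RBMX (-0.52) fell. With total-count scaling the medians of the 3 splicing lists shrank to -0.06, -0.07 and -0.17. Camera still called each, but it compares a list with the other genes, and rescaling shifts all genes nearly alike. Those calls therefore do not show that the lists fell under that scaling.

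Genes of DNA replication and the G1/S transition fell for 22 of 36 tested and rose for 2 (27 and 4 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 2.13e-07; adjusted p = 0.213 with an estimated correlation). CDC6, which loads the replicative helicase, fell by 0.75 on the log2 scale, RRM1 by 0.59, TYMS by 0.58 and MCM7 by 0.51. Mitosis and G2/M genes fell for 25 of 34 and rose for 1 (26 and 2 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 3.44e-09; adjusted p = 0.213 with an estimated correlation), among them HMMR (-0.91), DLGAP5 (-0.74), BUB1 (-0.64) and NUSAP1 (-0.62). Histone genes could be matched for 15 of 42 members; of 14 tested, 13 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 3.63e-07; adjusted p = 0.296 with an estimated correlation). HIST1H2BL (-0.84), HIST1H4C (-0.65), HIST1H1E (-0.64) and HIST1H1C (-0.57) fell. In control 3 the medians of these 3 lists lay below controls 1 and 2 by log2 differences of -0.20, -0.32 and -0.47, and against control 3 alone the knockout medians were -0.20, -0.20 and -0.19. Total-count scaling gave medians of -0.14 for G1/S and -0.29 for G2/M.

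Interferon-stimulated genes rose for 22 of 36 tested and fell for 1 (23 and 1 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 3.95e-09; adjusted p = 0.106 with an estimated correlation; 0.61 against control 3 alone). SAMD9 went from 62.5 ± 15.4 to 332 ± 8.63 normalized counts, RSAD2, an antiviral enzyme, from 44.0 ± 7.20 to 190 ± 23.5, and CMPK2 rose by 1.15. Antigen presentation genes rose for 7 of 17 tested and fell for 0 (7 and 0 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.00149; adjusted p = 0.176 with an estimated correlation; 0.83 against control 3 alone). The peptide transporter subunits TAP1 (1.30) and TAP2 (0.79), HLA-E (0.80) and cathepsin CTSS (1.46) rose, while the class II gene HLA-DRA had 3 reads in all 6 libraries together. NF-kB targets rose for 12 of 25 tested and fell for 2 (13 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.000846; adjusted p = 0.106 with an estimated correlation; 0.37 against control 3 alone). RELB, a subunit of NF-kB, rose by 2.44 (SE 0.22) on the log2 scale, and BIRC3 (2.34), TNFAIP2 (0.76) and IRF1 (0.72) rose. The GC and length correction lowered the NF-kB median to 0.25 (camera adjusted p = 0.0120), and without control 3 that of antigen presentation to 0.52.

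Myeloid markers rose for 9 of 14 tested and fell for 0 (10 and 0 adjusted over the list alone), with a median of 1.51 (camera adjusted p = 1.14e-05; adjusted p = 0.106 with an estimated correlation; 0.90 against control 3 alone, which differed from controls 1 and 2 by 0.02). ITGAM, the integrin CD11b, went from 9.42 ± 2.80 to 97.2 ± 9.52 and lysozyme LYZ from 580 ± 54.1 to 1139 ± 37.8. S100A9 rose from 1.16 ± 1.23 to 38.4 ± 5.90 and S100A8 from 0.991 ± 1.30 to 26.5 ± 5.15. Most of the listed genes were low: 14 of 18 lay under 10 normalized counts in the controls. Their median was 3.41 in the controls and 10.8 in the knockout. The list's median log2 fold change was 0.98 with the filter of at least 50 in 3 libraries, which is the value of LYZ itself. It was 0.87 with a pseudocount of 5. B-cell identity genes rose for 3 of 20 tested and fell for 0 (3 and 0 adjusted over the list alone), with a median of 0.18 that missed the threshold (camera adjusted p = 0.0576). The 3 were CD24 (1.57), SPI1 (1.21), a transcription factor of both myeloid and B cells, and POU2F2 (0.95).

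In 3 further lists more members rose than fell. Immediate early genes and the SOCS family rose for 13 of 35 and fell for 4 (14 and 4 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00729; adjusted p = 0.223 with an estimated correlation). FOSL2 (1.87), DUSP5 (1.51) and SOCS1 (1.36) rose and SOCS3 (-0.80) fell. B-cell receptor signalling genes rose for 9 of 27 tested and fell for 1 (10 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0193; adjusted p = 0.171 with an estimated correlation). Those that rose included INPP5D (1.71), PTPN6 (1.42), MALT1 (0.81) and PLCG2 (0.69), which other blood cells also express. BCL2 family and apoptosis genes rose for 10 of 27 and fell for 1 (10 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0194; adjusted p = 0.171 with an estimated correlation). BIRC3 (2.34) and BCL2L1 (0.44), which oppose cell death, and BOK (1.51) and BMF (1.44), which promote it, rose. After a correction for transcript GC content and length, added once control 3 had been seen to stand apart, camera's adjusted p was 0.252, 0.252 and 0.0510 for these 3 lists in the order given, with medians of 0.07, 0.03 and 0.10. Total-count scaling raised the medians to 0.40, 0.37 and 0.28. Against control 3 alone their medians were 0.23, 0.03 and 0.24, and control 3 differed from controls 1 and 2 by 0.13 and 0.11 for the first 2. Without control 3 the BCL2 family median was 0.03 and its call was lost (camera adjusted p = 0.0735), and B-cell receptor signalling lost its call without control 2 (camera adjusted p = 0.0520).

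**Figure D4:**
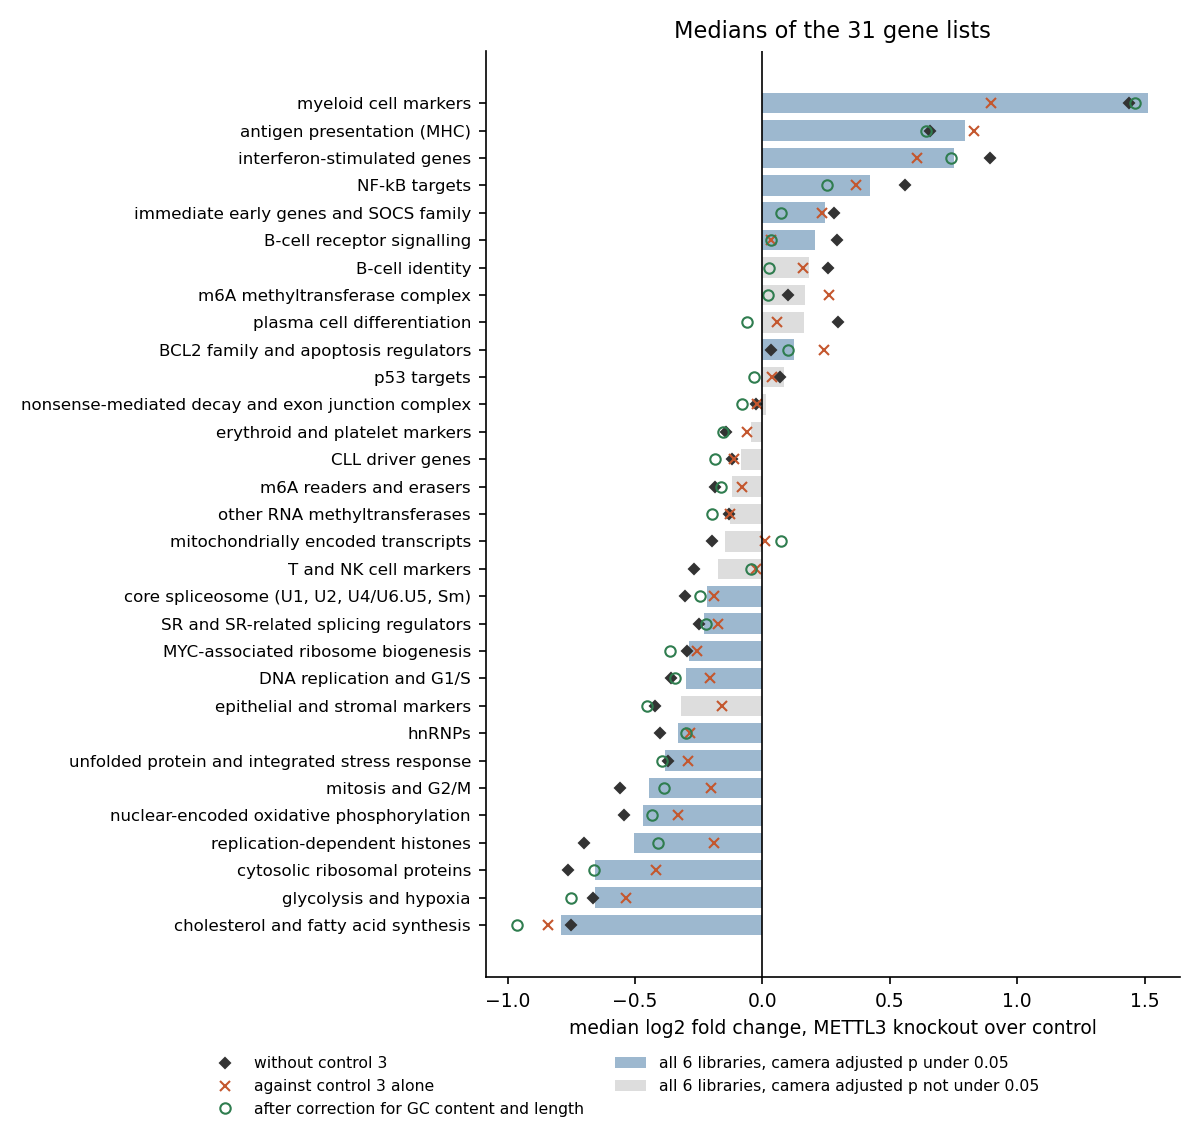
Median log2 fold change of the knockout over control (horizontal axis) for each of the 31 gene lists, with bars for all 6 libraries (blue, camera adjusted p under 0.05; grey, not under 0.05). Diamonds leave out control 3, crosses use control 3 alone and open circles follow correction for GC content and length; for myeloid markers the bar is at 1.51 and the cross at 0.90.

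The remaining lists did not pass. In the m6A methyltransferase complex 2 of 8 members rose and 1, METTL3, fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.421). RBM15B (0.41) and CBLL1 (0.40) rose, but RBM15B was at 0.09 and lost its call after the GC and length correction (limma-trend adjusted p = 0.557). Of 16 m6A readers and erasers 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0616), with YTHDF2 (0.45) higher and HNRNPC (-0.54) and HNRNPA2B1 (-0.46) lower. Other RNA methyltransferases rose for 3 of 20 and fell for 5 (3 and 5 adjusted over the list alone; camera adjusted p = 0.0721), with METTL16 (0.46) higher and METTL5 (-0.58) and DIMT1 (-0.53) lower. Nonsense-mediated decay genes rose for 2 of 23 and fell for 6 (4 and 6 adjusted over the list alone; camera adjusted p = 0.377); the list's median was 0.01 and its mean -0.03. PYM1 (0.45) rose, and MAGOHB (-0.53) and ATF4 (-0.39) fell. Targets of p53 rose for 2 of 27 tested and fell for 5 (2 and 5 adjusted over the list alone; camera adjusted p = 0.946), with TP53INP1 (1.48) higher and BBC3 (-0.72) and CCNG1 (-0.60) lower.

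CLL driver genes rose for 6 of 27 and fell for 9 (6 and 10 adjusted over the list alone; camera adjusted p = 0.262), with MYD88 (0.67) higher and RPS15 (-0.65) and POT1 (-0.59) lower. Mitochondrially encoded transcripts rose for 1 of 13 and fell for 2 (1 and 2 adjusted over the list alone; camera adjusted p = 0.370), the falls being MT-CO2 (-0.57) and MT-CO3 (-0.49), the latter lost without knockout replicate 3 (limma-trend adjusted p = 0.0520). The rise was that of MT-ND1 (0.37, limma-trend adjusted p = 0.0311), whose values overlapped between the groups. Its call was lost when any library other than control 3 was left out. Plasma cell genes rose for 3 of 14 tested and fell for 2 (3 and 2 adjusted over the list alone; camera adjusted p = 0.851), with XBP1 (-0.53) lower. Among the rises, FKBP11 (0.54) lost its call when any library other than control 3 was left out. PRDM1 (0.69) lost its call without control 2 or knockout replicates 1 or 2. The fall of SEC11C (-0.47) was lost without knockout replicate 2 and with total-count scaling. T and NK cell markers rose for 3 of 15 tested and fell for 4 (3 and 5 adjusted over the list alone; camera adjusted p = 0.421), with TRBC1 (-0.93) lower. Erythroid and platelet genes fell for 3 of 11 tested and rose for 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.285), among them AHSP (-0.58). ITGA2B (-0.48) passed narrowly (limma-trend adjusted p = 0.0406), and its call was lost under 8 alternatives, such as TMM scaling (0.0670) and leaving out any of the knockout replicates (0.148, 0.0753 and 0.117). Epithelial and stromal markers rose for 1 of 13 tested and fell for 5 (3 and 5 adjusted over the list alone; camera adjusted p = 0.116), with KRT18 (-0.84) and KRT8 (-0.70) lower and FN1 (0.97) higher.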

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

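The filter of a mean of at least 10 and the GC and length corrections were chosen after the result was seen. METTL3 kept its sign under every setting. The 19 lists called with a preset correlation kept theirs under every setting run for lists. Lists were not run with the authors' deposited test. The cause of each lost or gained call was not tested. All 6 libraries gave 3513 genes higher and 3248 lower. Total-count scaling gave 1858 lower, and 181 lower at least 2-fold against 340. The filter of at least 50 gave 2623 higher and 3266 lower, and left 512 higher and 126 lower at least 2-fold. The genes lower by at least 2-fold numbered 179 among protein-coding genes, 189 with a pseudocount of 5 and 217 in the authors' deposited table. Correction for GC content and length without control 3, chosen after seeing the data, gave 4628 higher and 5821 lower.

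Leaving out 1 library at a time gave 2274 to 5520 genes higher and 1877 to 5220 lower, both highest without control 3, and 210 to 447 lower at least 2-fold. METTL3 ranged from -0.42 to -0.30, with its call lost without knockout replicate 3, and was at -0.20 under total-count scaling. List medians ranged from -0.18 to -0.11 for m6A readers and erasers, -0.16 to -0.10 for other RNA methyltransferases, 0.17 to 0.32 for B-cell receptor signalling, 0.0340 to 0.204 for the BCL2 family, -0.214 to -0.0352 for mitochondrial transcripts and 0.15 to 0.30 for B-cell identity, each crossing camera's threshold in at least 1 of these fits. Medians of lists called in none of these fits ranged from -0.0742 to 0.0165 for nonsense-mediated decay, -0.143 to 0.0501 for erythroid genes and -0.424 to -0.0866 for epithelial markers.

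With an estimated correlation camera called no list. The medians, which this setting does not change, were -0.22 for the core spliceosome, -0.23 for SR proteins, -0.33 for hnRNPs, -0.66 for ribosomal proteins, -0.29 for ribosome biogenesis, -0.30 for G1/S, -0.45 for G2/M, -0.50 for histones, -0.38 for the stress responses, -0.66 for glycolysis, -0.47 for oxidative phosphorylation, -0.79 for lipid synthesis, 0.12 for the BCL2 family, 0.21 for B-cell receptor signalling, 0.42 for NF-kB targets, 0.75 for interferon-stimulated genes, 0.79 for antigen presentation, 0.25 for immediate early genes and 1.51 for myeloid markers. By fry, histones missed the threshold (median -0.50, adjusted p = 0.0539), and m6A readers (-0.12), other RNA methyltransferases (-0.13), nonsense-mediated decay (called lower, with a mean of -0.03 but a median of 0.0124), B-cell identity (0.18) and epithelial markers (-0.32) passed it.

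Without a filter on low values, m6A readers (-0.12), other RNA methyltransferases (-0.13) and B-cell identity (0.18) passed; with limma-voom, m6A readers (-0.12) and B-cell identity (0.28); with a pseudocount of 0.1, B-cell identity (0.19). Among protein-coding genes the BCL2 family (0.12) and B-cell receptor signalling (0.21) were lost. Correction for GC content and length ended the calls of the BCL2 family (0.10), B-cell receptor signalling (0.0341) and immediate early genes (0.0712), and brought in m6A readers (-0.16), other RNA methyltransferases (-0.20) and CLL drivers (-0.19). NF-kB targets kept their call at 0.25, and the B-cell identity median, not called, was 0.0275 (camera adjusted p = 0.252). The same correction without control 3 left the 3 lost lists at 0.0496, 0.0619 and 0.0225, and called m6A readers (-0.15), other RNA methyltransferases (-0.14), CLL drivers (-0.21), erythroid genes (-0.27) and epithelial markers (-0.54); RBM15B turned to -0.0557 (adjusted p = 0.399, limma-trend). Total-count scaling turned the sign of 5 medians of lists that were not called, and shrank called medians such as those of the core spliceosome (-0.06) and SR proteins (-0.07).

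Same-numbered libraries correlated in their deviations at 0.0401, -0.0446 and -0.00643, which gave no sign of pairing by replicate number. The knockout libraries differed little beyond counting error (mean chi-square per gene 1.46 to 1.85, against 5.98 to 44.6 among controls). These correlations therefore cannot show that the samples were unpaired. With the replicate block 3625 genes were higher and 3210 lower. Fold change rose with transcript length across genes, not independent replicates, at a Spearman correlation of 0.0904 over all tested genes, 0.0513 in protein-coding genes and 0.133 with the filter of at least 50. Depth was lowest in knockout replicate 1, where 1 read is worth 1.59 normalized counts.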

Other observations

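All tests here other than the splits of the samples were chosen after the results were seen. In the 6 libraries, genes of other parts of the erythroid program were also abundant: GATA1, chosen like HBE1 and HBZ after its value was seen, averaged 5513 ± 146 normalized counts in the controls and 4192 ± 117 in the knockout, HBE1, embryonic globin, 3605 ± 130 and 3025 ± 307, and HBZ 3433 ± 93.2 and 2144 ± 132 (SD, n = 3 each). CEBPE, a transcription factor of granulocyte maturation and also chosen after its value was seen, went from 2.76 ± 1.40 to 380 ± 26.2.

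The first pattern is the scarcity of many B-cell genes beside several abundant erythroid genes. Loss of B-cell genes through the knockout is argued against by the controls, since 0 of the B-cell identity genes reached 100 normalized counts there and were lower in the knockout, and the controls' median was 5.18. For the B-cell identity list, the levels argue against B cells as the source. In the controls 16 of its 28 genes lay under 10 normalized counts, though 7 reached 100 or more. In all 6 libraries together 4 of them had 0 reads. A candidate explanation is that the libraries, or the file, come from cells of another lineage than the label. Which lineage stays open, since the B-cell median of 5.18 against 17.6 for the erythroid list only restates the pattern. No table here holds a second HG3 profile, so an exchange of cells, libraries or files was not tested. No biological explanation was tested.

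The second pattern is control 3, which lies apart from controls 1 and 2. Sequencing depth is argued against, since controls 1 and 3 were close in depth (17.8 and 15.5 M reads) and control 2 was not (43.2 M), while the SD between controls 1 and 3 was 1.98 times that between controls 1 and 2. Knockout cells mixed into control 3 are argued against by 100 genes raised at least 4-fold, which showed a median share of 0.0101 of the knockout difference in control 3 (quartiles -0.0281 and 0.0926), against a slope of 0.285 over all genes. A library difference that follows GC content may be part of it (Spearman correlation 0.581 across genes). After correction for GC and length the spread of control 3 stayed 1.72 times that between controls 1 and 2, so it is not the whole. The knockout mean followed GC content against controls 1 and 2 (0.399) but not against control 3 (-0.006). Along GC content, controls 1 and 2 thus stood apart from control 3 and the knockout mean. Without control 3 this tilt cannot be told apart from the knockout. What else set control 3 apart was not tested.

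The third pattern is the rise of myeloid genes. Myeloid cells mixed into the knockout libraries were examined through LYZ, S100A8, S100A9, MPO, ELANE and FCN1, abundant in mature or immature myeloid cells. The median of their rises was 0.0400 of that of MYO1F, though LYZ rose by 559 counts, more than the 434 of MYO1F. By the median of the 6 genes the mixture would be argued against, and by the largest rise, that of LYZ, it would not. That summary and its bound were settled after the values were seen. MYO1F was itself picked as the largest rise in these data, which favours a low share. The mixture is therefore left undecided. A GC and length difference between libraries is argued against by a list median of 1.46 after correction (camera adjusted p = 1.58e-05). A hypothesis that stays open is that myeloid genes may have been switched on in the labelled knockout cells, by the loss of METTL3 or by the isolation of the line; the design has no second knockout line to tell these apart.

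Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In 1 split, the real one, limma-trend called 6761 genes, and the highest of the other splits called 0; at an unadjusted p of 0.05 the real split had 9555 and the others 257 to 1270, and limma-voom called 7414 and 0. At least 2-fold changes numbered 1856 in the real split, the 1 split with as many, and 0 at most in the others. Each other split mixes both labels on each side, so any difference between the labels enters its spread and lowers its calls. The comparison therefore cannot tell an effect of the knockout from another difference between the groups.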
